A study of Homo sapiens with 2 samples.

How the data were processed

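RNA from 1 culture of parental HCC827 cells and 1 culture of the gefitinib-resistant line HCC827 ZDR3 was selected for polyadenylated transcripts and sequenced on an Illumina HiSeq instrument, per the labels' protocols. The growth protocol in the labels describes medium for isotope labelling of proteins in 2 cell lines and does not say whether the sequenced cells grew in it. TopHat is named in the submitters' processing notes. Its version, the genome build, the counting tool, the strand setting and whether reads were paired are not given in the sources used here.

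The deposited table gives 1 log2 value per gene and library for 20985 genes with a symbol and an Ensembl identifier, and its name describes the values as RPKM. The deposited log2 values were tested against that name. In each library the back-transformed values were whole multiples of 1 step that was the same for every gene, so the values were reads per gene times 1 factor per library and not divided by gene length. The step was 0.00700 for the parental and 0.00727 for the resistant library. The 3504 and 3573 genes at the lowest value stood at 0.9 reads and were taken as genes without reads. Of the genes with 1 to 100000 reads, 17090 in the parental and 17049 in the resistant library, 100% came out whole within 0.1 read in both. Above that limit the deposited decimals fix a count less exactly. Read counts summed to 257192607 and 243549869. Levels of different genes within a library are therefore not corrected for length, while plain ratios between the libraries are unaffected by length. The pseudocount and the minimum level used below act on these uncorrected levels. At low levels the log2 ratio, and whether a gene counts as expressed, thus depend in part on gene length. The 12 mitochondrially encoded genes in the table had 0 reads in both libraries. The column for the parental library carries the line's name with the ending Prim, which was read as the parental line since the other column names ZDR3.

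The comparison had been laid out for RPKM values before the data were examined, and it was applied as written to the back-transformed values, with 0 for genes without reads. The log2 ratio was log2((resistant + 1)/(parental + 1)), which understates the ratio of low genes, and genes with a level of at least 1 in at least 1 library were called expressed. The pseudocount of 1 equals more than 100 reads, so a gene without reads and one at the floor of 3 reads have almost the same log2 ratio. With 1 library per group there was no test. Count-based tools were not used. The precision from counting alone was given by exact 95% binomial (Clopper-Pearson) intervals of the ratio of unadjusted levels. For the 102 named genes with at least 1000 reads in both libraries the widest such interval reached 7.17% to either side. Intervals and floors cover counting error only, and reads without molecular identifiers are not independent molecules. Spread between cultures is unknown.

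A set of 43 gene lists with 956 entries was fixed before the data were examined. Of these 950 were found by symbol, and 29 genes stood in more than 1 list. For each list with at least 5 expressed members the median log2 ratio was placed among 10000 random lists of the same size, matched on mean level in 20 bins. A percentile under 2.5 or over 97.5 was called outside the range. Such percentiles describe these 2 libraries and test no condition. Of the marker lists of other cell types, the parental library itself expressed 9 of 15 basal and squamous, 4 of 21 leukocyte, 3 of 13 fibroblast, 2 of 11 endothelial and 2 of 15 neuroendocrine genes.

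The genes named were set by a rule fixed in advance: EGFR and JUN, the 12 expressed genes with the largest increase and the 12 with the largest decrease, up to 4 expressed members of each list with the largest absolute log2 ratio, and a set of receptor and AP-1 genes with CDH1, VIM, ZEB1 and BCL2L11. Some genes that the rule takes are not reported here. Genes named in the closing part on chromosome runs, on neighbours of ABCB1 and on a kidney, liver and intestine list were chosen after their values were seen. The same holds for VOPP1, OS9 and CDK4 and for the cell cycle genes MCM2, MCM3, MCM5, CCNE2, E2F1 and TYMS.

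Gene order along chromosomes, transcript length and GC content were taken by Ensembl identifier from GENCODE release 29, which need not be the authors' annotation, so no coordinates are given. Of the expressed genes 13476, or 97.8%, had a position. Runs of genes with shifted ratios were found by an optimal partition of each chromosome's log2 ratios, held to within 2 of 0, with at least 5 genes per run and a penalty of 26.4 per break. This gave 11 breaks, and 20 shuffles of gene order gave at most 0. The runs were sought after a first look at neighbouring genes.

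The fold count was tested on simulated data made from the mean levels of the real genes, with counting noise only. Of 200 genes changed 4-fold among 13435 expressed genes in the comparison of resistant with parental cells, 100% of the increases and 92% of the decreases passed the 2-fold threshold, and 0 unchanged genes did. The missed decreases reflect the pseudocount. Counting noise at this depth could hardly take an unchanged gene past the threshold, so that 0 says nothing about spread between cultures. The list percentile was tested on the real ratios. Of 200 random lists of 20 genes 15 were called outside the range, and 198 were called after a shift of 0.75 was added to their log2 ratios.

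Alternatives comprised pseudocounts of 0.1 and 5, rescaling to the same total or the same 75th percentile, centring on the median, other minimum levels, thresholds of 1.5-fold and 4-fold, random lists not matched on level and list means. A correction for GC content and length and a subtraction of neighbouring genes were added after the data had been seen. Genes that share reads with near-identical copies, such as AKR1C1 and AKR1C2, IFITM and HLA genes, UGT1A forms and ribosomal proteins, are uncertain, as are overlapping genes on opposite strands. Sex-linked marker genes were left out of the text. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.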

Results

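The transcriptomes of a parental lung adenocarcinoma line and of a gefitinib-resistant derivative were compared by sequencing of polyadenylated RNA. HCC827 is an established line with an activating EGFR mutation, and gefitinib is an inhibitor of the EGFR tyrosine kinase. The derivative, HCC827 ZDR3, came from cells kept in gefitinib that began at 10 nM for 1 month and was raised 3-fold per month to 1 µM, after which 3 colonies were picked. Each group held 1 library, so no difference has a replicate check, no p-value is given, and every difference is one between these 2 libraries. The labels do not say whether gefitinib was present when the resistant cells were harvested. The parental library held 257192607 gene reads and the resistant library 243549869. Levels are given in normalised reads, in which 1 unit stands for 143 reads in the parental and 138 reads in the resistant library. The log2 ratio is resistant over parental after 1 unit was added to both levels.

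The series title names EGFR signalling and JUN, and both genes were examined before any other. EGFR (ENSG00000146648) was not lower in the resistant library: its level was 6662 in the parental and 7182 in the resistant library, a log2 ratio of 0.11. JUN (ENSG00000177606), a subunit of the AP-1 transcription factor, was higher in the resistant library, at 232 against 49.1, a log2 ratio of 2.22 and a ratio of 4.74 with an exact 95% counting interval of 4.61 to 4.86. That interval, like the others given here, covers counting error only. JUN lay in a run of 55 neighbouring expressed genes on chromosome 1, from RNF11 to CYP2J2, of which 51 had ratios above 0, with a median log2 ratio of 1.62. JUN exceeded the median of this run by 0.60. With the median of the 20 nearest expressed genes on each side subtracted, the log2 ratio of JUN was 1.52. That window reaches past the end of the run, which lowers the median subtracted.

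**Figure D1:**
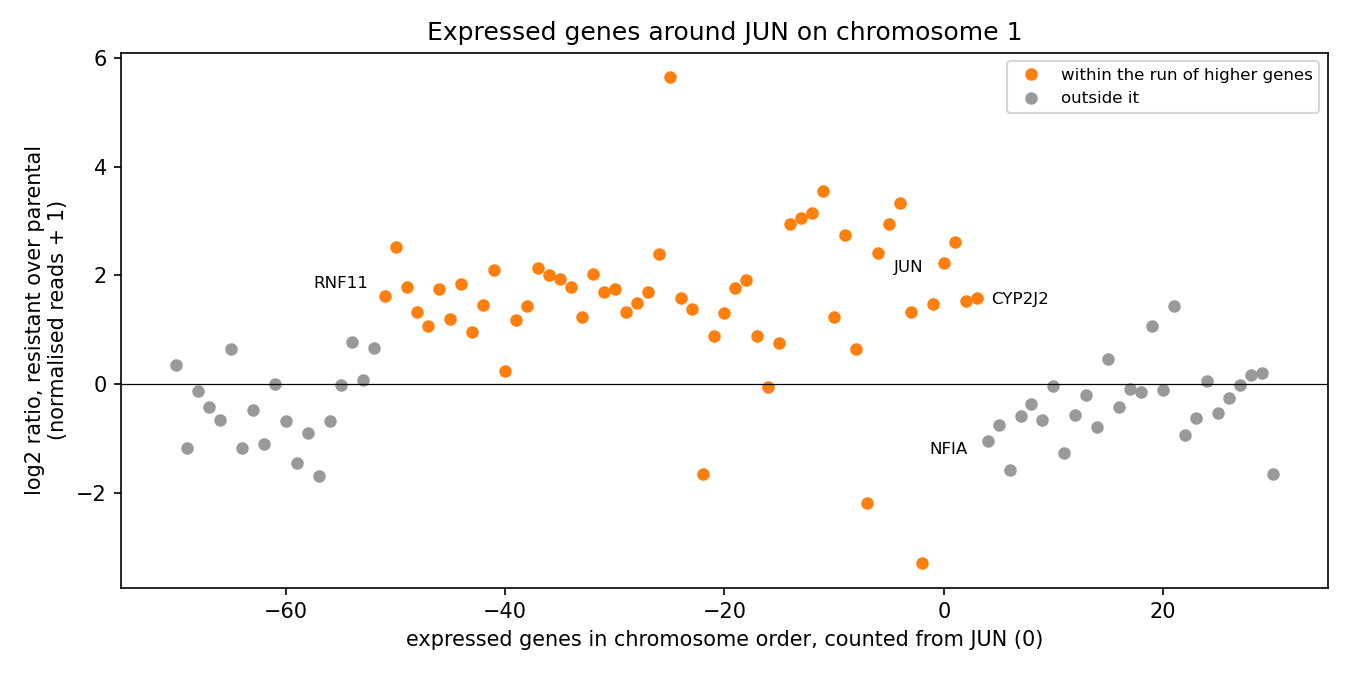
Log2 ratio of expressed genes around JUN on chromosome 1, in chromosome order, with each point 1 gene, the x axis counting expressed genes from JUN and the y axis giving the log2 ratio of resistant over parental normalised reads plus 1. Orange points are the 55 genes of the run from RNF11 to CYP2J2, with a median of 1.62, and grey points are genes on either side of it.

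The partner receptors of EGFR were lower. ERBB3, a kinase-impaired receptor that couples ERBB dimers to PI3K, was at 338 in the parental and 62.2 in the resistant library (log2 ratio -2.42), and ERBB2 stood at 529 and 202 (-1.38). The ubiquitin ligase CBLB was also lower (-1.36), while LRIG1, a negative regulator of ERBB receptors, was higher (1.02). Of the 13 expressed ERBB receptors and adaptors, 1 was at least 2-fold higher and 3 at least 2-fold lower, and the median of -0.37 lay within the middle 95% of random lists matched on level. The 8 expressed ERBB ligands had a median of 0.67, at percentile 98.7 of the random lists. Among them EREG (epiregulin) was at 169 and 769 (2.18), HBEGF at 2.35 and 6.94 (1.24) and TGFA at 31.6 and 53.4 (0.74), while EGF was lower (-2.47). The list lay inside the random range with a minimum level of 5 (median 0.61) and by its mean (0.45). EREG lay in a run of 115 genes on chromosome 4 with a median log2 ratio of 0.90.

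Other AP-1 genes went both ways. FOSL1, a FOS-family partner of JUN, was higher, at 267 in the parental and 719 in the resistant library (1.43), and FOSL2 had a log2 ratio of 0.43. JUNB (-0.58), JUND (-0.23), FOS (-0.63), JDP2 (-0.81) and BATF2 (-1.25) had lower levels in the resistant library. ATF3 was at 42.1 and 41.5, a difference within its counting interval. The 15 expressed members of the AP-1 family had a median of -0.02, within the random range, with 2 members at least 2-fold higher and 1 at least 2-fold lower.

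Across the 13777 genes with a level of at least 1 in at least 1 library, 1463 were at least 2-fold higher and 1333 at least 2-fold lower in the resistant library, with a median log2 ratio of -0.03. At least 16-fold differences were seen for 79 genes in the higher and 118 in the lower direction. The 12 genes with the largest increases were led by ALDH1A1, a retinaldehyde dehydrogenase, at 1.14 in the parental and 1905 in the resistant library (9.80). They also held the tight junction gene CLDN2 (8.68), the bromodomain gene BRDT (7.98), the multidrug efflux pump ABCB1 (7.72, from 0.707 to 358), the scaffold PDZK1 (7.49) and the tumour suppressor gene DLC1 (6.99). The remaining members were IGFBP7 (6.80), GSG1 (6.63), CYFIP2 (6.47), IQGAP2 (6.41), CAPN6 (6.39) and C14orf105 (6.19). GSG1 rested on 2 parental reads, which puts its ratio of 7099 within a counting interval of 1965 to 58623.

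The 12 largest decreases were led by the gel-forming mucin MUC5B, at 1701 in the parental and 0.392 in the resistant library (-10.26), and the calcium-binding gene CALB1, at 602 and 0.167 (-9.01). AGR2, a disulfide isomerase needed for mucin folding, had a log2 ratio of -8.40, and the epithelial transcription factor EHF one of -8.31. S100A9 (-8.12), CHI3L2 (-7.98), TNIP3 (-7.85), the membrane mucin MUC4 (-7.62), TMPRSS4 (-7.43), S100A14 (-7.39), GPR110 (-7.37) and SCEL (-7.37) completed the set.

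**Figure D2:**
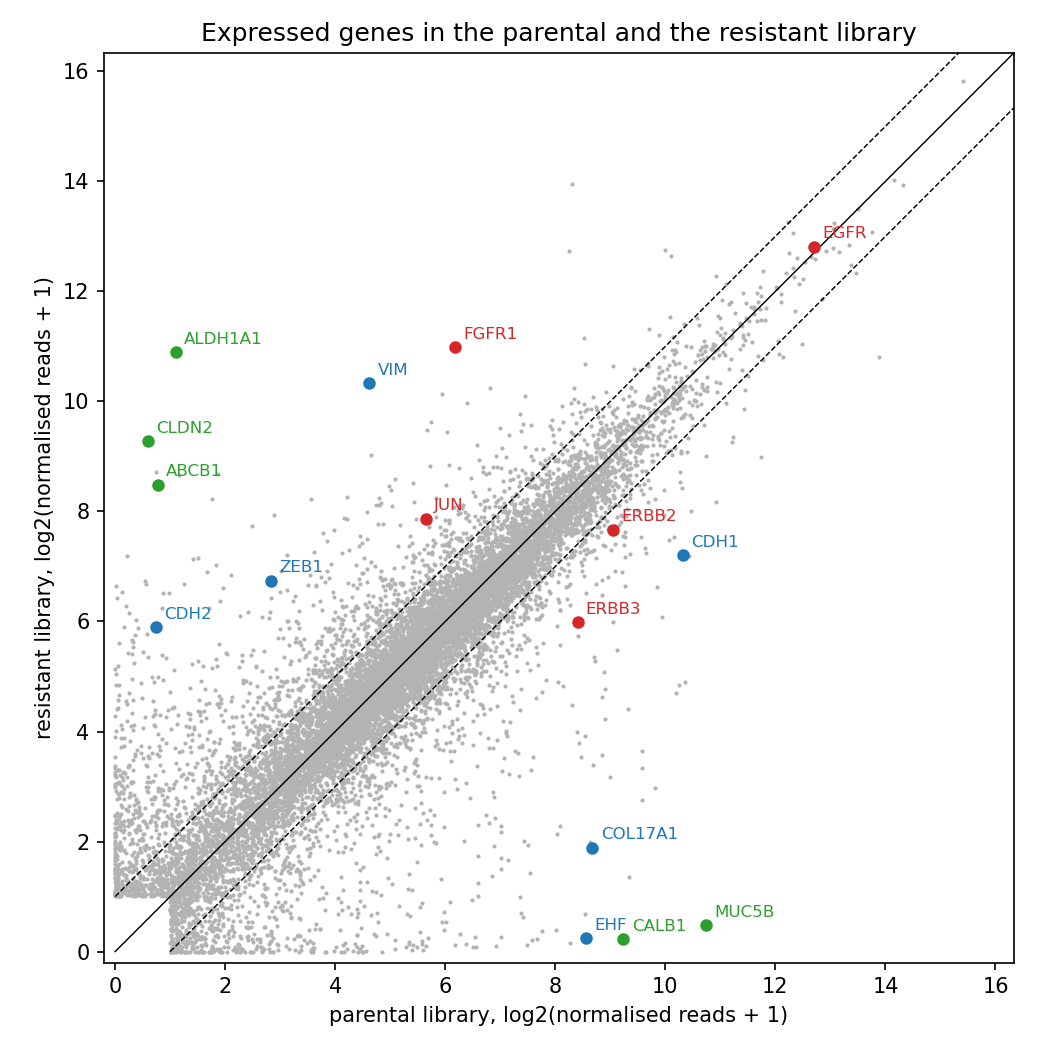
Level of each of the 13777 expressed genes in the parental (x axis) and the resistant library (y axis), both as log2(normalised reads + 1), with a solid line at equal levels and dashed lines at 2-fold differences. Red marks receptor genes and JUN. Blue marks epithelial and mesenchymal genes and the hemidesmosome collagen COL17A1, and green marks further genes of the largest differences. EGFR lies near equality (0.11), JUN above it (2.22) and MUC5B far below it (-10.26).

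Epithelial junction and keratin genes were lower as a group. Of 33 expressed members 25 were at least 2-fold lower and 0 at least 2-fold higher, and their median of -2.59 lay below all 10000 random lists. Besides EHF, the transcription factor GRHL2, which maintains epithelial gene expression, was at 89.3 in the parental and 0.0581 in the resistant library (-6.42), the clathrin adaptor AP1M2 had a log2 ratio of -5.94 and the serine protease PRSS8 one of -5.58. CDH1, the gene of E-cadherin, was at 1271 and 146 (-3.11), so it remained expressed.

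Mesenchymal genes diverged. Of 25 expressed members 10 were at least 2-fold higher and 9 at least 2-fold lower, and the median of 0.02 was within the random range. The intermediate filament gene VIM was at 23.5 in the parental and 1289 in the resistant library (5.72), the N-cadherin gene CDH2 at 0.672 and 58.4 (5.15), and the transcriptional repressor ZEB1, which silences CDH1, at 6.10 and 106 (3.91). COL6A2 was also higher (3.89). It lay at the end of chromosome 21 in a run of 18 genes, from ADARB1 to PRMT2, of which 18 were higher with a median of 2.65. In the same list MMP14 (-3.72) and COL6A3 (-3.71) were lower.

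Of 18 expressed TGF-beta response genes, 4 were at least 2-fold higher and 3 at least 2-fold lower. Their median of 0.58 was at percentile 99.96, though the mean of the list (0.44) lay within the range of random means. THBS1, at 6.41 in the parental and 244 in the resistant library (5.04), CTGF (1.83) and CYR61 (1.39) were higher. The 22 YAP-TEAD response genes had a median of 0.29, at percentile 98.3, with 7 members at least 2-fold higher, among them ANKRD1 (2.82) and AMOTL1, at 27.2 and 112, and 3 at least 2-fold lower, with IGFBP3 (-5.48) and F3 (-4.05) the lowest. The mean of this list (0.13) was within the range of random means.

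Integrin and laminin genes were lower in part. Of 24 expressed members 11 were at least 2-fold lower and 4 at least 2-fold higher, with a median of -0.40 at percentile 0.38. The hemidesmosome collagen COL17A1 was at 407 in the parental and 2.70 in the resistant library (-6.79). ITGB6 (-4.93) and ITGB4 (-3.82), the hemidesmosome integrin subunit, were lower too. The list's median moved inside the random range with a pseudocount of 5 (-0.26) and with each other minimum level (-0.21 to -0.27). The 13 expressed metalloproteinase and plasminogen activator genes had a median of -0.45, just within the random range at percentile 2.71. Of these 3 were at least 2-fold higher and 2 at least 2-fold lower. The highest were the protease inhibitor genes of the list, SERPINE2 (3.81), TIMP2 (1.51) and TIMP1 (1.39), and the lowest was the metalloproteinase MMP14 (-3.72).

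Lung lineage genes were lower for the most part. Of 11 expressed alveolar and airway genes 7 were at least 2-fold lower and 2 at least 2-fold higher, with a median of -1.96 below all random lists. The mucin MUC1 was at 457 in the parental and 10.96 in the resistant library (-5.26), and SLC34A2 (-5.22) and CEACAM6 (-4.09) were lower as well. ABCA3, the surfactant lipid transporter, was higher (3.62). Without a minimum level the list's median was -0.06 and within the random range, since 9 of its 20 members were below the minimum.

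Among the marker lists of other cell types fixed in advance, the basal and squamous list alone had enough expressed members for a median. Its 9 expressed genes had a median of -2.65, below all random lists, and 7 of them were at least 2-fold lower and 0 at least 2-fold higher. The stem and squamous transcription factor SOX2 was at 187 in the parental and 8.81 in the resistant library (-4.26), and DSC3 had a log2 ratio of -3.12. TP63, the regulator of basal cells, and PKP1 had 0 reads in the resistant library, which made them at least 770-fold and 277-fold lower against a floor of 3 counts. Of 21 leukocyte genes 4 were expressed, with CD68 at 155 and 320 (1.04), CD14 at -1.26, LST1 at -0.79 and CSF1R at -0.68. Of 13 fibroblast genes 3 were expressed, with FBLN1 higher (3.14) and COL6A3 and COL1A1 (-1.88) lower. Of 11 endothelial genes 3 were expressed, with ROBO4 at -1.22, EGFL7 at -0.69 and TIE1 at 0.69. Of 15 neuroendocrine genes 3 were expressed, namely ENO2 (2.09), DLL3 (1.37) and SCG5 (-1.30). These 4 lists give single values only.

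Receptor tyrosine kinases other than the ERBB family went both ways. FGFR1 was at 71.4 in the parental and 2028 in the resistant library (4.81) and FGFR3 at 11.6 and 101 (3.01). EPHA1 was at 10.8 and 0.0218 (-3.53), where the resistant value rested on 3 reads and the ratio of parental over resistant of 494 had a counting interval of 169 to 2397, and ROS1 was lower (-2.40). MET, whose amplification is a known route to gefitinib resistance in this line, had a lower level in the resistant library, at 1531 and 960 (-0.67). AXL (-0.58) and IGF1R (-0.48) had lower levels as well. Of 20 expressed members 4 were at least 2-fold higher and 5 at least 2-fold lower, and the median of -0.53 was at percentile 0.17. The mean of the list, -0.17, and the median without a minimum level, -0.07, lay within the random range. The 15 expressed ligands of these receptors had a median of -0.20, within the range, with KITLG (1.90) and PDGFC (1.11) higher and GAS6, a ligand of AXL, lower (-1.75). IGF1 had 226 parental reads and 0 resistant reads, at least 72.6-fold lower. That median was 0.61, above the random range, with a minimum level of 5.

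Output genes of the ERK pathway diverged. DUSP6, an ERK phosphatase induced by ERK, was at 44.9 in the parental and 7.05 in the resistant library (-2.51), and the feedback inhibitor SPRY1 was lower (-1.65), while MYC (1.58, from 532 to 1593) and EPHA4 (2.07) were higher. Of 20 expressed members 4 were at least 2-fold higher and 2 at least 2-fold lower, with a median of 0.21 within the random range. Among 16 JNK and stress kinase components the median was 0.12, also within it, with 3 members at least 2-fold higher and 2 at least 2-fold lower. MAPK13 (p38 delta) was lower (-4.98) and DUSP10 was lower (-1.21), while the phosphatase DUSP1 (3.06) and MAPK10 (JNK3, 2.89) were higher. The 18 PI3K-AKT components had a median of -0.07 within the range, with PIK3R3 lower (-3.09), PIK3CD higher (1.18) and PIK3R2 at 0.98.

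Cell cycle genes had lower levels as a group in the resistant library, though single members ranged from -1.88 to 0.61. Of 30 expressed members 11 were at least 2-fold lower and 0 at least 2-fold higher, and the median of -0.75 was below all random lists. TOP2A was at 2403 in the parental and 652 in the resistant library (-1.88), CDK1 at 223 and 77.8 (-1.51), the proliferation marker MKI67 at 389 and 153 (-1.34) and CCNB2 at 75.9 and 30.1 (-1.31). The fall was not uniform: MCM2 (-0.002), MCM5 (0.03), MCM3 (0.06), CCNE2 (0.06) and E2F1 (0.08) lay near 0, and TYMS was the highest member (0.61). CDK inhibitor and senescence genes had a median of -0.56 over 13 members, at percentile 0.45, but their largest values went both ways. IGFBP7 was among the largest increases and IGFBP3 was at 1166 and 25.1 (-5.48), while CDKN1C (1.53) and CDKN2D (1.19) were higher. The mean of that list was 0.03, and its median with a pseudocount of 5, -0.29, lay within the random range. The 23 expressed p53 targets had a median of 0.05 within the range, with 2 at least 2-fold lower, FAS (-1.36) and POLH (-1.10). DDB2 was at 25.3 in the parental and 12.2 in the resistant library, and TP53I3 had a log2 ratio of 0.98. Of 19 replication-dependent histone genes only 8 were expressed in these libraries of polyadenylated RNA, with a median of -0.60, within the range. HIST2H2BE (-2.04), HIST2H2AA3 (-1.23), HIST1H2BC (-1.23) and HIST2H2AC (-0.73) were the largest values of that list.

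BCL2, the anti-apoptotic founder of its family, was at 0.231 in the parental and 41.6 in the resistant library (5.11). BOK was higher (1.58), and BCL2A1 (-2.97) and the pro-apoptotic BMF (-1.87) were lower. BCL2L11, the gene of BIM, which mediates cell death on EGFR inhibition, had a log2 ratio of -0.81, from 44.2 to 24.8. The 15 expressed family members had a median of -0.23, within the random range, with 3 at least 2-fold higher and 2 at least 2-fold lower.

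Interferon, antigen presentation and cytokine genes were lower in part. Of 34 expressed type I interferon response genes 10 were at least 2-fold lower and 1 at least 2-fold higher, with a median of -0.71 below all random lists. IFITM3 (-3.72), IFI27 (-2.96), IFITM1 (-2.90) and OAS1 (-2.29) had the largest differences, though IFITM genes are close in sequence and can share reads. Of 22 antigen presentation genes 8 were at least 2-fold lower and 0 at least 2-fold higher, and these included the class II genes CD74 (-6.05, from 71.2 to 0.0872), HLA-DRA (-5.56), HLA-DRB1 (-5.19) and HLA-DMA (-3.86). The median of that list was 0.03, within the random range, while its mean was -1.21, below the random means. NF-kB and cytokine genes had a median of -0.95 over 22 expressed members, below all random lists, with 11 at least 2-fold lower and 4 at least 2-fold higher. The neutrophil chemokines CXCL1 (-5.30) and CXCL5 (-2.74) were lower, while IL32 (4.67) and CSF2 (3.83) were higher.

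Drug transporters and xenobiotic enzymes took opposite directions. Besides ALDH1A1 and ABCB1, the glutathione transferase GSTA1 was higher (4.83, from 2 reads to 3825 reads), whereas ALDH1A3 was at 761 in the parental and 11.5 in the resistant library (-5.93). Of 24 expressed members 7 were at least 2-fold higher and 5 at least 2-fold lower, with a median of -0.40 at percentile 0.82, while the mean of 0.57 was outside in the opposite direction, at percentile 98.7 of the random means. Its median was inside the random range with a pseudocount of 5 (-0.18) and with a minimum level of 5 (-0.38). The 22 targets of NRF2, the regulator of antioxidant genes, had a median of -0.30, within the range at percentile 2.95. Of these 7 were at least 2-fold lower, with NQO1 at 339 and 52.5 (-2.67) and ABCC2 at -1.66, and 3 at least 2-fold higher, with AKR1C2 (2.44) and AKR1C1 (1.70), which are near-identical in sequence and can share reads.

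Metabolic and stress lists had medians within the random range. Among 25 cholesterol synthesis genes, with a median of -0.20, 2 were at least 2-fold higher and 1 at least 2-fold lower. LSS, the lanosterol synthase gene, was at 97.2 in the parental and 491 in the resistant library (2.33), and it lay in the run on chromosome 21. The median of the fatty acid synthesis list was -0.17, with ACACA (2.54, from 1101 to 6391), the acetyl-CoA carboxylase gene, FADS3 (1.60) and ACACB (1.49) higher and SREBF1 lower (-1.31). Of 31 expressed glycolysis and hypoxia genes, with a median of 0.07, 4 were at least 2-fold higher and 4 lower, led by CA12 (5.22), ANGPTL4 (3.29), EGLN3 (-2.74) and ALDOC (-2.12). The 25 genes of ER stress and the amino acid response had a median of -0.09, with VLDLR (1.40) and DDIT3 (1.22) higher and PHGDH (-1.25) and SLC7A11 (-1.25) lower. The 14 heat shock genes had a median of -0.04, with CRYAB (3.13) higher, DNAJB1 (-1.77) and BAG3 (-1.03) lower and HSPH1 at 0.64.

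Wnt genes had a median of 0.28 over 12 expressed members, within the range, with AXIN2 (1.76) and ZNRF3 (1.11) higher and WNT7A (-1.54) and FZD8 (-1.09) lower. Notch genes had a median of 0.35 over 10, also within it, with NOTCH3 (-4.73) and NOTCH2 (-1.02) lower, HEY1 (2.25) higher and HES4 at 0.83. The 9 expressed genes of a stem-like cell list had a median of -0.31, within the range. PROM1 had 331 parental reads and 0 resistant reads, at least 106-fold lower, NT5E was at -1.40, ALCAM at -0.98 and SOX4 at -0.44.

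Genes used by most cells differed little. The 25 housekeeping genes had a median of -0.21 and 41 oxidative phosphorylation genes one of 0.06, both within the random range, and 0 genes of either list differed by 2-fold or more. Among the largest ratios were SDHA (0.77), ATP5O (0.67), COX7B (-0.67) and COX7C (0.62) in the second list and, besides SDHA, PGK1 (-0.50) and VCP (-0.47) in the first. The 72 ribosomal protein genes had a median of 0.10, at percentile 98.6, but at percentile 94.4 of random lists that were not matched on level. Of these 3 were at least 2-fold higher and 0 at least 2-fold lower, with RPL5 at 1.36, RPS28 at 1.29 and RPL13 at 0.82. RPS28 lay in a run of 74 genes on chromosome 19, from VAV1 to CDKN2D, of which 70 were higher with a median of 1.31, and RPL5 in a run of 69 genes on chromosome 1 with a median of 0.75. Other named genes in such runs were ANGPTL4 and CDKN2D on chromosome 19, BRDT and CYR61 in the run of RPL5, and IGFBP7, MAPK10, CXCL1 and CXCL5 in the run of EREG, of which CXCL1 (-5.30) and CXCL5 (-2.74) were lower, against the run.

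Genes near EGFR on chromosome 7, 11 of them expressed, had a median log2 ratio of 0.03, with LANCL2 at 0.56, SEC61G at -0.49, PHKG1 at -0.40 and PSPH at 0.32. The 9 expressed genes near MET had a median of 0.42. FOXP2 (5.41), CAV2 (1.35) and TFEC were at least 2-fold higher, TFEC at least 84.1-fold from 0 parental reads, and CAV1 was at 0.84. Both medians lay within the random range.

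**Figure D3:**
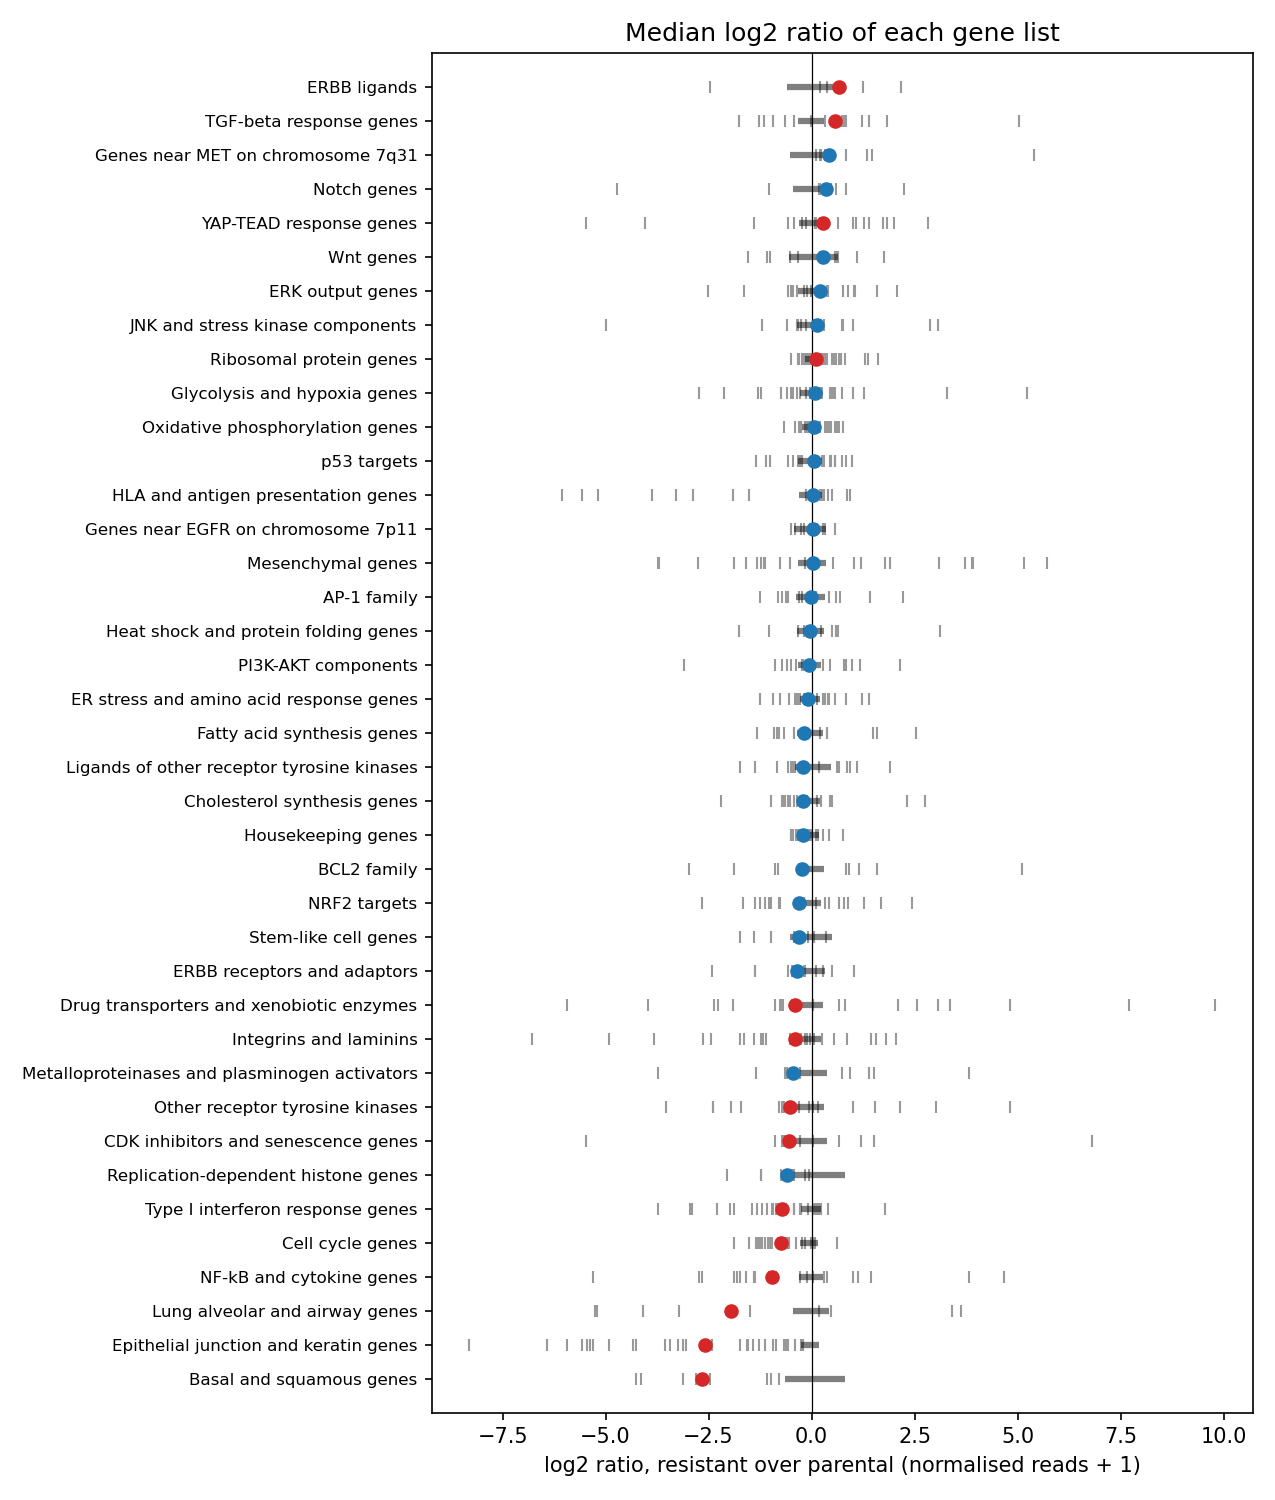
Median log2 ratio of resistant over parental normalised reads plus 1 for 39 gene lists with at least 5 expressed members (points), with grey ticks for the expressed members and dark bars for the middle 95% of 10000 random lists matched on level. Red points lie outside the bar and blue points within it. The epithelial list lies at -2.59, the cell cycle list at -0.75 and the ERBB ligands at 0.67.

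In all, 14 of 39 lists lay outside the middle 95% of random lists, 10 below and 4 above, where the 95% range alone would put about 1.95. In the check on random lists, 15 of 200 were called outside. Both figures hold for unrelated genes, whereas members of a list can move together and 29 genes stood in more than 1 list. Of the 14, 5 lay outside it under every other setting that gave a value, and these were the epithelial, basal and squamous, cell cycle, interferon and NF-kB lists. There were 12 such settings, except for the basal and squamous list, which had too few members with a minimum level of 1 in both libraries. The 3 rescalings among them shift a list and its random lists almost alike. With neighbouring genes subtracted, the medians of the ERBB ligands (0.53), the other receptor tyrosine kinases (-0.25), the CDK inhibitors (-0.16) and the drug transporters (-0.20) moved inside the random range. Of the 25 lists inside it, 11 lay outside under at least 1 other setting. These were the ERBB receptors, ERK output, cholesterol and oxidative phosphorylation lists with neighbours subtracted, the ligands of other receptors and the antigen presentation genes as given above, and the NRF2, Notch, histone, metalloproteinase and MET neighbour lists under other choices.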

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

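The correction for GC content and length and the subtraction of neighbouring genes were chosen after the data had been seen; the other settings were fixed before. The counts of 1463 higher and 1333 lower genes became 901 and 865 with a pseudocount of 5, 2585 and 2581 at a threshold of 1.5-fold, and 482 and 434 at 4-fold, as the construction of these settings implies; under the other settings both stayed within 1.5 times. The share of higher genes among both ranged from 50.04% to 56.3%. The log2 ratio of EGFR was 0.13 after rescaling to the same total, 0.18 at the same 75th percentile, 0.14 after centring and 0.40 after subtraction of its neighbours, and so was above 0 throughout. That of JUN was 2.13 with a pseudocount of 5, 2.29 at the same 75th percentile and 1.52 after subtraction of its neighbours. For JUN these neighbours reach past the end of its run, whose median it exceeded by 0.60. The epithelial median stayed below the random range under all 12 alternatives, of which the 3 rescalings shift a list and its random lists almost alike, and the mesenchymal median stayed within it, at 0.00 without a minimum. The median of ligands of other receptors turned to 0.61 with a minimum of 5. As means rather than medians, the CDK inhibitor list gave 0.035, the antigen presentation list -1.21 and the drug transporter list 0.57, each of opposite sign to its median, and 7 further lists, inside the random range by both, also differed in sign. The RPS28 log2 ratio turned to -0.042 after subtraction of its neighbours. Of 1368 values of the 196 other genes named by the rule, 1363 kept their sign, but 573 moved by more than the counting interval. Besides RPS28, the values that did not keep their sign were values of ATF3, which lay near 0. Otherwise the cause was not tested. The planned mean over several table rows of a symbol gave no value of its own, since each symbol had 1 row. The basal and squamous list gave no value with a minimum of 1 in both libraries. Depth limited few results: genes with 3 or fewer reads in a library, such as EPHA1, HLA-DRA, GSG1, GSTA1 and WNT7A, have wide counting intervals.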

Other observations

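The tests of admixture, of scaling between the libraries and of the segment around JUN, the correction for GC content and length, and the search for runs of genes were chosen after the result they concern had been seen. A kidney, liver and intestine list of 60 genes was written after CLDN2, PDZK1, NR1H4 and another gene had been seen among the higher genes but before its own values were. Of its 33 expressed members 16 were at least 2-fold higher in the resistant library and 8 at least 2-fold lower. The transporters SLC17A3 (4.60) and SLC3A1 (3.48, from 30.4 to 350), the sodium pump regulator FXYD2 (4.26), the urea cycle gene CPS1 (2.85), angiotensinogen AGT (2.79) and the protease inhibitor SERPINA1 (2.63, from 365 to 2262) were higher. MUC13 (-4.62), HPN (-3.06) and ANPEP (-2.66) were lower. PAX2, a kidney transcription factor, had 0 parental and 561 resistant reads. The median of 0.79 lay above all 10000 random lists but under the value of 1 set in advance for a wider programme of this kind, so these values leave open whether the line took on such a programme. NR1H4, which helped to prompt the list, had a log2 ratio of 5.89.

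The expressed genes moved together with their neighbours along chromosomes. Over 637 windows of 41 genes the standard deviation of the window medians was 0.289, where 100 shuffles of gene order gave at most 0.121. The highest window, from KTI12 to PRKAA2 on chromosome 1, had a median of 1.69 with 92.7% of genes above 0, and the lowest, from NMI to NOSTRIN on chromosome 2, had -0.80 with 82.9% below 0. There were 6 runs of at least 10 genes with a median of at least 1.5-fold, which held 3.21% of the expressed genes with a position and 16.7% of those at least 2-fold higher, 239 of 1435. A candidate explanation is a difference in DNA copy number between the parental culture and the resistant clone, and a spread above that of the shuffles is what it predicts. No DNA was measured, and shared regulation of neighbours was not tested.

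JUN lies 3 expressed genes from the end of the run from RNF11 to CYP2J2, and 45 of the run's 55 genes were at least 2-fold higher. The 20 nearest expressed genes on each side of JUN had a median of 0.70, between the bounds of 0.5 and 1 set for the test, because that window reaches across the end of the run; the 5 nearest on each side had a median of 1.502. The ratio of JUN exceeded the median of the run by 0.60. A gain of the segment may therefore contribute to the higher JUN level, as a hypothesis that DNA data on these cells would settle, and regulation of JUN itself stays open. For ABCB1 the 12 expressed genes starting within 1 Mb had a median of 0.046, which argues against a gain of that whole segment, although the adjoining ABCB4 (4.65) and RUNDC3B (3.72) were higher with it. The genes near MET had a median of 0.42, opposite in sign to MET at -0.67, which argues against a loss of that segment, and the genes near EGFR had a median of 0.029 beside 0.11 for EGFR, a difference too small to assign.

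Epithelial genes were lower by a median of -2.59 in the resistant library. Cells of another type mixed into that culture would dilute every transcript they lack or express less. EGFR and the 11 expressed genes near it had a median of 0.069. That median cannot decide, because it rests partly on less abundant genes, such as PSPH at 375 and 468. Other cells may express these at a like level. Of the very abundant genes, VOPP1 beside EGFR was at 7770 in the parental and 6836 in the resistant library, and SEC61G at 3033 and 2157. Among all genes by reads, VOPP1 ranked 14 and 15, EGFR 17 and 12, and SEC61G 54 and 89. OS9 and CDK4 on chromosome 12 stood at 20568 and 15655 and at 6391 and 6327. These abundant genes fell far less than the epithelial median or not at all. This argues against admixed cells that lack them or express them much less, but not against cells with like levels of them. A correction for GC content and length left the epithelial median at -2.58, which argues against that trend as the cause. Whether both libraries carry the same sequence variants was not analysed here. The selection in gefitinib, a chance property of the picked colony and drift in culture all stay open, and these cannot be separated with 1 library per group.

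Cell cycle genes had a median of -0.75 and the random lists matched on level one of -0.056, a difference of -0.69, and the middle 95% of these random lists lay from -0.28 to 0.17. Scaling between the libraries moves genes of like level alike, so the distance from the random lists argues against scaling as the cause. Under the 3 rescalings the difference changed by at most 0.00223, which follows from that property and adds no evidence. A rescaling test planned before, in which the median was -0.68 at most, could not decide this, because list and random lists move together. A slower growth of the culture was not tested, and the selection in gefitinib, the picked colony and drift stay open here too.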
